A study of Rattus norvegicus with 16 samples.

How the data were processed

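RNA from the CA1 and CA3 fields of rat organotypic hippocampal slice cultures, that is, slices of brain tissue kept alive in culture, was measured on 16 Affymetrix rat expression arrays. The labels give 2 regions, 4 time points (T0, T30m, T3h and T12h, read here as 0, 30 min, 3 h and 12 h) and 2 biological replicates of each, which makes 8 groups of 2 arrays. The series title names oxidative stress as the subject; the agent, its dose and the relation of T0 to it are not given in the sources used here. Per the labels' protocols, total RNA was extracted by the array manufacturer's procedures and carried a biotin label put in over 2 cycles, a method that amplifies RNA before hybridization.

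The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, gives all arrays the same distribution of probe signals and summarises the probes of a probe set on the log2 scale; its version and settings are not given in the sources used here. The table holds 15923 probe sets with values from 2.82 to 14, and the array medians lie between 5.811 and 5.938. Because the distributions were equalised, a change in the total amount of mRNA per cell cannot be seen in these values, and each change is relative to the other genes of the array. The precision is limited by the number of arrays.

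After 57 control probe sets were set aside, 15866 probe sets were tested. The platform annotation gave 1 gene for 12783 of them, several for 312 and none for 2771. Of the named probe sets, 12748 matched a gene of the rat RefSeq table (assembly GRCr8, used for names only) through the Entrez identifier, and this changed 0 symbols. For the 10411 genes, the probe set with the highest mean over all arrays stands for the gene; 1868 genes have several. Of the named genes that passed, 7 have 10 other probe sets, which give 15 values over the contrasts. Of these values 1 passed, for Trib3 and in the same direction. The other probe sets of Cd93, Ptprc and Sqstm1 lie near 0, between -0.08 and 0.22, so these calls rest on 1 probe set each. Those of Cd93 and Ptprc have low mean log2 values (4.2 and 3.8). The other probe set of Top2a, with a mean of 4.1, lies between -0.62 and -0.38, against -2.65 to -1.85 for the one used. That of Rgs4 lies at 1.95, against 4.3 for the one used.

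The values were fitted with limma 3.58.1 in R 4.3.3, with 8 group means, no covariate, 8 residual degrees of freedom and an empirical Bayes prior worth 2.55. Contrasts were CA1 minus CA3, each later time minus T0 in each region and averaged over both, and the difference of these changes between the regions. Adjusted p-values are Benjamini-Hochberg values over all probe sets within a contrast, and adjusted p under 0.05 was the threshold. In each contrast, 793 probe sets would be expected to have an unadjusted p under 0.05 by chance alone. Counts of such probe sets given below are to be read against this number. Probe sets vary together, so a count can stray from it without a real difference. Errors after ± are moderated standard errors on the log2 scale unless called SD. Gene lists, 39 in all with 679 of 831 genes measured, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The lists, the comparisons, the rule for naming genes and the other settings to be tried were fixed before the data were examined.

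The replicate numbers were checked for pairing. Deviations from the group means correlated between the CA1 and CA3 arrays of the same time and number, over probe sets, at 0.57 for T0, 0.67 for T30m, 0.58 for T3h and 0.57 for T12h, so the numbers were taken to pair the regions within a time; the labels do not say what a number marks. Between T0 and a later time they ran from -0.24 to 0.31, with 5 of 12 under 0.1, and between later times from 0.3 to 0.66, with 0 of 12 under 0.1. The GAPDH 3' minus 5' signal was higher in replicate 2 in 8 of 8 groups. The later times thus share an effect of the number, while pairing with T0, which each time contrast uses, was not taken as given because not all of its correlations were over 0.1. The number as a block was kept as another setting. Further fits were therefore added after the data were seen: the 8 CA1 minus CA3 differences with 4 residual degrees of freedom for region contrasts, and the 8 pair means for changes averaged over both regions. They are called the pair fit. The labels call the replicates biological, without saying whether they came from separate animals.

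The fits were tested on simulated data with the real means and spreads, in 5 data sets of 15866 probe sets with 200 changed in each. Deviations were drawn independently between probe sets. Where pairs shared deviations, they did so to the same degree for all probe sets. With independent arrays, the change at 12 h in CA1 was recovered for 35.6% of the probe sets changed 2-fold, 74.8% of those changed 4-fold and 87.6% of those changed 8-fold. For the 12 h change averaged over both regions, with the arrays of a pair sharing deviations, the fit of all arrays made 36.2% false calls among its calls, and the pair fit 5%, while recovering 13.2% of 2-fold and 68.8% of 4-fold changes. For CA1 minus CA3 with shared deviations, the fit of all arrays made 0.7% false calls and recovered 80.4% of 2-fold changes, and the pair fit made 5.9% and recovered 86.8%.

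Named genes follow a rule with these parts: up to 10 genes per direction with the largest change among those past the threshold with no overlap between the arrays of the groups compared or, for averaged contrasts, with the same sign in each region or time; of each list, the 4 largest changes past the threshold and up to 2 members nearest to it; a fixed set of 14 genes for region and 27 for time, of which 12 and 25 were measured; and the 5 smallest p-values where fewer than 5 genes passed. The first part, with the same sign in all 8 pairs, was applied to the pair fit of the region contrast after its values were seen.

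Other settings fixed beforehand were an intensity trend or a robust prior in the empirical Bayes step, the replicate number as a block, only probe sets above the median level, cyclic loess between arrays, array weights, only the arrays of the groups compared, the mean of all probe sets of a gene, and leaving out each array. Added after the data were seen, besides the pair fit, were the mean signal of the 12 poly-A spike probe sets or the GAPDH 3' minus 5' signal as a covariate, and leaving out the arrays that stand apart in these signals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.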

Results

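The series asked how the CA1 and CA3 fields of the rat hippocampus respond over time to oxidative stress. CA1 pyramidal neurons are known as the more vulnerable of these neurons and CA3 pyramidal neurons as the more resistant. Expression was measured in organotypic hippocampal slice cultures, which keep neurons, glia and much of the local wiring of the tissue. RNA was taken at T0, 30 min, 3 h and 12 h in both regions, with 2 arrays per region and time and 16 arrays in all. The 2 arrays of a group correlated across probe sets at 0.911 to 0.969, and the CA1 and CA3 arrays of the same time and replicate number, called a pair here, at 0.963 to 0.988.

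Control signals differed between times. Probe sets for Bacillus control transcripts, which the manufacturer's protocols add to RNA before labelling, had a mean log2 signal of 6.57 at T0, 5.37 at 30 min, 5.96 at 3 h and 4.79 at 12 h (n = 4 arrays each). The arrays ran from 4.103 to 6.851. Low values fell in pairs: at 30 min, replicate 2 read 4.421 in CA1 and 4.103 in CA3, against 6.266 and 6.681 in replicate 1. The hybridization control BioB, which ran from 6.148 to 10.62, was low there too (6.148 in CA1 and 6.526 in CA3). It was also low on the 12 h replicate 2 arrays (6.88 and 6.393). CA3 T0 replicate 1 was low in BioB (6.765) but not in the spike signal (6.607). The spike signal may thus hold more than RNA input or amplification. The difference between the GAPDH 3' and 5' probe sets, which grows when RNA is degraded or shortened, ran from 1.292 to 3.928 and was highest in the 3 h replicate 2 arrays of both regions (3.928 in CA1 and 3.927 in CA3). The first principal component held 39.7% of the variance. On it the 30 min and 3 h arrays of replicate 1 lay between -43.7 and -26.5, and those of replicate 2 between 16.8 and 35.8. The T0 arrays lay between -40.1 and -8.1 and the 12 h arrays between 10.1 and 55.9. The component thus parted the replicates at 30 min and 3 h.

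**Figure D1:**
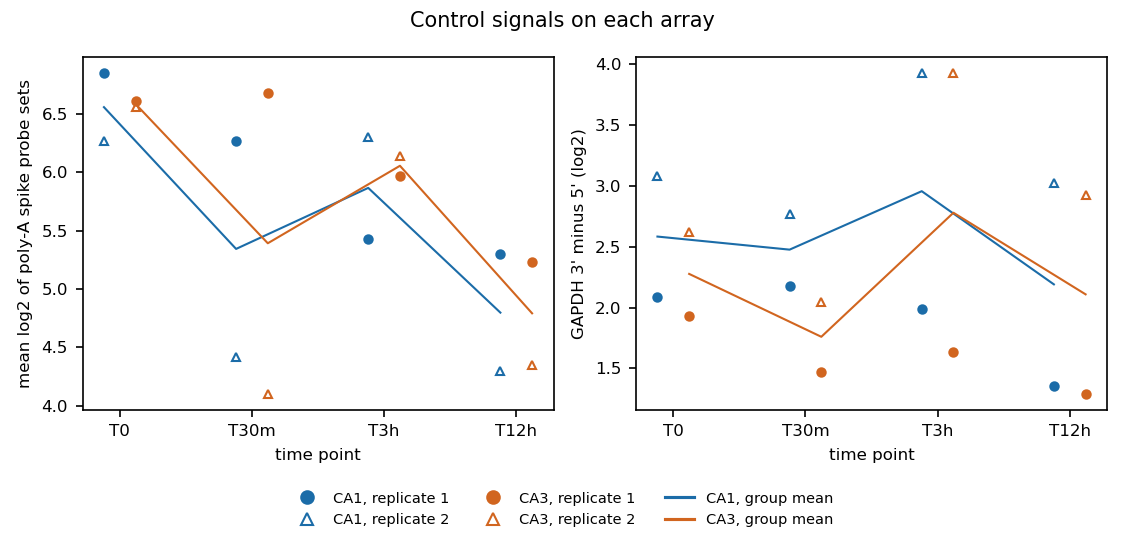
Control signals on each array, with time point on the horizontal axis. The left panel gives the mean log2 signal of the poly-A spike probe sets and the right panel the GAPDH 3' minus 5' log2 difference. Points are arrays, lines join group means, and the replicate 2 arrays of 30 min and 12 h lie between 4.103 and 4.421 on the left.

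The region comparison asked which genes differ between CA1 and CA3. Myelin and oligodendrocyte genes were lower in the CA1 samples. In the pair fit, CA1 minus CA3 over 8 pairs was -1.12 ± 0.15 for Mbp, the myelin basic protein (adjusted p = 0.0433), -1.14 ± 0.11 for Mag, the myelin-associated glycoprotein (adjusted p = 0.0113), and -0.95 ± 0.14 for Cldn11, the claudin of myelin tight junctions (adjusted p = 0.0464), each lower in CA1 in 8 of 8 pairs. Pcp4, a calmodulin-binding peptide of CA2 and dentate neurons, was lower in CA1 by 1.54 ± 0.13 in size (adjusted p = 0.0104, 8 of 8 pairs). Fzd2, a Wnt receptor, was higher in CA1 by 0.93 ± 0.13 and Fxyd1, a regulator of the sodium pump, by 0.71 ± 0.1 (adjusted p = 0.0433 for each, 8 of 8 pairs). The same sign in all 8 pairs was part of the rule that named genes from the pair fit, so it is no separate evidence.

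Of the 11 measured oligodendrocyte markers, 3 were lower in CA1 in the pair fit, 0 were higher and the median difference was -0.59. Adjusted over the list alone, 10 were lower. The list passed camera (adjusted p = 1.48e-12) and held with an estimated correlation in the fit of all arrays (adjusted p = 0.0459), but not in the pair fit (adjusted p = 0.0893 with an estimated correlation). Outside the list, the myelin membrane proteins Pllp (-1.02 ± 0.11) and Tspan2 (-0.95 ± 0.13) and the choline phosphodiesterase Enpp6 (-1.01 ± 0.15) were also lower in CA1 in the pair fit. The other non-neuronal lists differed less, with medians of 0.15 over 14 astrocyte, 0.03 over 16 microglia and 0.01 over 11 endothelial and mural cell markers, -0.09 over 6 oligodendrocyte precursor and -0.21 over 12 fibroblast, meningeal and choroid plexus markers. The last list passed camera in the pair fit (adjusted p = 0.0312), not in the fit of all arrays (adjusted p = 0.0548; adjusted p = 0.672 with an estimated correlation). Gfap, the astrocyte intermediate filament gene, differed by 0.24 ± 0.12 (adjusted p = 0.54, pair fit). Endothelial and mural cell markers such as Abcb1a, Vwf and Flt1 had low mean log2 values (3.6, 4.2 and 4.6, against array medians from 5.811 up). A difference in those cells could thus be missed.

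Averaged over the 4 times, most pyramidal neuron markers lay in the direction of their field, but not at each time. The 8 measured CA1 markers had a median of 0.54, with 7 higher in CA1, and the 8 CA3 markers a median of -0.21, with 1 higher (camera adjusted p = 0.00111 and 0.0018; adjusted p = 0.324 and 0.413 with an estimated correlation). None of their members passed over all genes in either fit, and adjusted over the list alone 5 CA1 markers were higher and 3 CA3 markers lower in CA1 in the pair fit. The CA1 list's median was below 0 in 3 of 8 pairs and the CA3 list's in 7 of 8. By time, the CA1 list's median was 0.02 at T0, 0.54 at 30 min, 0.01 at 3 h and 1.46 at 12 h, and the CA3 list's -0.22, -0.18, -0.22 and -0.31. Of the fixed markers, Wfs1 differed by 0.44 ± 0.14, Fibcd1 by 0.55 ± 0.23, Mpped1 by 1.02 ± 0.35 and the CA3 kainate receptor subunit Grik4 by -0.83 ± 0.15 in the pair fit, with adjusted p = 0.246, 0.422, 0.303 and 0.0818. Wfs1 was 0.26 without the replicate 2 arrays of 30 min and 12 h, and Fibcd1 0.26 without those of 3 h. Mpped1 had a mean of 4.42 in CA1 and 5.47 in CA3 at T0, and of 9.72 and 6.5 at 12 h. The 10 general excitatory neuron markers had a median of -0.52, all lower in CA1 (camera adjusted p = 0.00111; adjusted p = 0.638 with an estimated correlation).

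In the fit of all 16 arrays, which leaves the pairing out, 0 probe sets passed for CA1 against CA3 over the 4 times (limma; 510 at an unadjusted p under 0.05). The pair fit gave 33, of which 7 were higher and 26 lower in CA1 (1679 at an unadjusted p under 0.05). These stand for 26 genes, 20 of them with the same sign in all 8 pairs. At T0 alone 0 passed in both fits (115 and 628 at an unadjusted p under 0.05). The leading genes there, none past the threshold, included Pcp4 (-2.32 ± 0.56), the neuronal microtubule regulator Stmn2 (-2.89 ± 0.82) and Nes, the intermediate filament of neural progenitors (0.91 ± 0.23). Of the 39 lists, 13 passed camera (5 higher and 8 lower in CA1), 21 in the pair fit, and 1 with an estimated correlation.

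**Figure D2:**
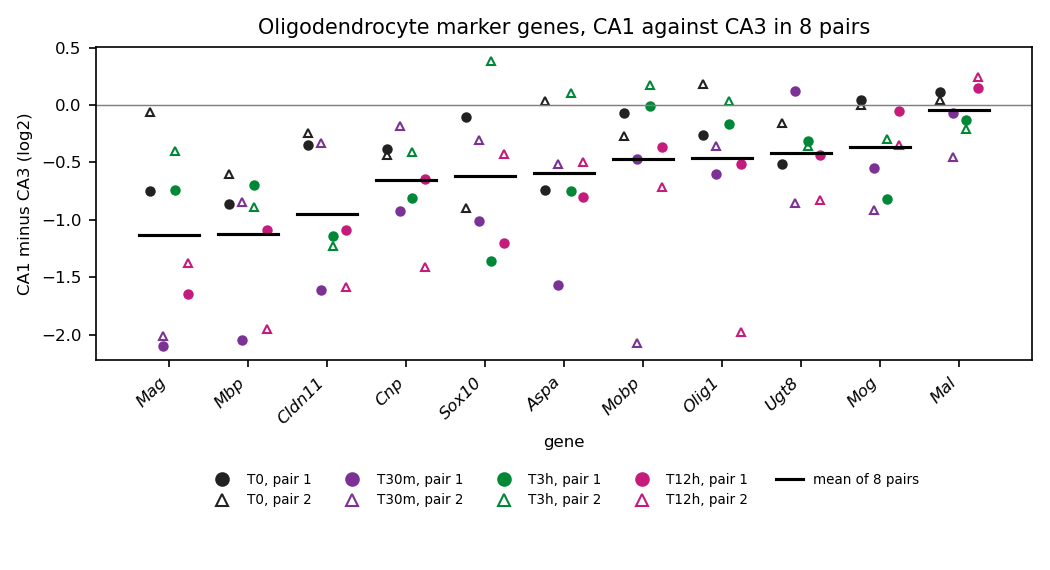
CA1 minus CA3 log2 difference (vertical axis) of the 11 measured oligodendrocyte markers (horizontal axis) in 8 pairs of arrays. Points are pairs, coloured by time, and black bars are means over the 8 pairs; Mbp and Mag lie below 0 in 8 of 8 pairs.

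At 30 min, several genes of dividing cells had fallen in the average over both regions, in the fit of all arrays. With pair means none passed (smallest adjusted p = 0.416). In the fit of all arrays, the mitotic regulator Pimreg fell by 2.23 ± 0.21, the proliferation marker Mki67 by 2.09 ± 0.26, the kinetochore gene Spc25 by 1.83 ± 0.23, the mitotic kinesin Kif15 by 1.78 ± 0.26 and the replicative helicase subunit Mcm3 by 1.16 ± 0.15 on the log2 scale (4 arrays against 4, adjusted p from 0.00957 to 0.0407). Nes fell by 1.27 ± 0.17 and Cd93, a receptor of myeloid and endothelial cells, by 3.02 ± 0.39 (adjusted p = 0.0196 for each). Zfp36, an immediate early gene whose protein destabilises AU-rich mRNAs, was the gene that rose, by 1.61 ± 0.16 (adjusted p = 0.00957).

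The 24 measured cell cycle genes were all lower at 30 min, with a median of -1. Of these 2 fell and 22 did not pass, and 17 fell when adjusted over the list alone (camera adjusted p = 2.76e-23; adjusted p = 0.0561 with an estimated correlation). Of 36 immediate early genes, 31 were higher, with a median of 0.59. Of these 1 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 1.85e-10; adjusted p = 0.272 with an estimated correlation). Values that did not pass were 2 ± 0.42 for Fos (adjusted p = 0.2), 1.08 ± 0.23 for Junb (adjusted p = 0.2), 1.55 ± 0.42 for Nr4a1 (adjusted p = 0.321) and 2.11 ± 0.93 for the neurotrophin Bdnf (adjusted p = 0.657). Without the replicate 2 arrays of 30 min and 12 h, Nr4a1 was 0.94 and Bdnf 0.61. The 30 cytosolic ribosomal protein genes had a median of -0.61 with 0 past the threshold (camera adjusted p = 1.13e-13; adjusted p = 0.493 with an estimated correlation). Microglia markers had a median of -0.55 beside these lists, and -0.08 without the replicate 2 arrays of 30 min and 12 h, where the spike signal was low. The immediate early gene median was then 0.26 and the cell cycle median -0.79.

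In all, 17 probe sets passed at 30 min averaged over both regions (1 higher and 16 lower). In CA1 alone 2 passed, Zfp36 (2.03 ± 0.23, adjusted p = 0.0284) and Pimreg (-2.73 ± 0.3, adjusted p = 0.0284), and in CA3 alone 0 (limma; 483 at an unadjusted p under 0.05), where Zfp36 was 1.19 ± 0.23 and Pimreg -1.74 ± 0.3. Averaging the CA1 and CA3 arrays of a pair left 0 probe sets averaged over both regions (limma; 629 at an unadjusted p under 0.05, smallest adjusted p = 0.416), and 0 passed without the low-spike replicate 2 arrays, without either 30 min array of CA1 or without CA1 T0 replicate 2. Leaving out 11 of the 16 arrays singly moved the count by over 1.5 times.

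At 3 h several cell cycle genes had fallen and 4 genes had risen in the average over both regions, in the fit of all arrays. With pair means none passed (smallest adjusted p = 0.28). In the fit of all arrays, Mki67 fell by 2.29 ± 0.26, Racgap1, a regulator of cytokinesis, by 2.26 ± 0.29, Pimreg by 2.1 ± 0.21, the DNA topoisomerase Top2a by 1.85 ± 0.22 and the mitotic kinase Melk by 1.76 ± 0.21 (adjusted p from 0.00835 to 0.0108). The 4 probe sets that rose were those of the growth arrest and stress genes Gadd45g (2.48 ± 0.39) and Gadd45b (2.26 ± 0.29), of Chac1, which degrades glutathione and is a target of the integrated stress response (1.49 ± 0.2), and of the aldehyde oxidase Aox1 (1.39 ± 0.19), with adjusted p from 0.0108 to 0.038. Cd93 fell by 2.62 ± 0.39 (adjusted p = 0.0307).

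Of the 24 cell cycle genes 3 fell, 21 did not pass and all were lower, with a median of -1.05. Of them 19 fell adjusted over the list alone (camera adjusted p = 2.46e-23; adjusted p = 0.0558 with an estimated correlation). Of 36 immediate early genes 2 rose, and the median was 0.58 (camera adjusted p = 2.95e-09; adjusted p = 0.348 with an estimated correlation). Atf3 was 2.41 ± 0.49 (adjusted p = 0.118) and Ddit3, the stress transcription factor CHOP, 1.47 ± 0.36 (adjusted p = 0.205; 0.81 without the replicate 2 arrays of 3 h), neither past the threshold. Of 33 unfolded protein and integrated stress response genes 1 rose, and the list did not pass (median 0.12, camera adjusted p = 0.115). None of the 22 measured targets of NRF2, the transcription factor of the antioxidant response, passed over all genes, and 2 rose adjusted over the list alone (median 0.1, camera adjusted p = 0.146). The peroxiredoxin repair enzyme Srxn1 was 1.56 ± 0.32 (adjusted p = 0.121) and the heme oxygenase Hmox1 1.36 ± 0.34 (adjusted p = 0.211). Microglia markers had a median of -0.62 (camera adjusted p = 0.0109; adjusted p = 0.665 with an estimated correlation), and -0.21 without the replicate 2 arrays of 3 h, which had the highest GAPDH 3' to 5' difference. The cell cycle median was then -0.9.

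At 3 h 29 probe sets passed averaged over both regions, 4 higher and 25 lower. With cyclic loess between arrays 42 passed, 12 of them higher. In CA1 alone 1 passed, Pimreg (-2.72 ± 0.3, adjusted p = 0.0469), and in CA3 alone 0 (limma; 623 at an unadjusted p under 0.05), with Gadd45b at 2.34 ± 0.41 and Chac1 at 1.72 ± 0.28 (adjusted p = 0.42 for each). Pair means left 0 averaged over both regions (limma; 792 at an unadjusted p under 0.05, smallest adjusted p = 0.28), as did leaving out the replicate 2 arrays of 3 h or the CA1 replicate 2 array of T0.

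At 12 h genes known from neurons, microglia and dividing cells were among those that had changed in the average over both regions, in the fit of all arrays. With pair means none passed (smallest adjusted p = 0.0541). In the fit of all arrays, Chac1 rose by 3.15 ± 0.2 (adjusted p = 0.000144), Gadd45b by 3.27 ± 0.29, Gadd45g by 3.41 ± 0.39 and the activity-dependent transcription factor Fosb by 3.14 ± 0.53. Neuronal genes that rose included the G protein regulator Rgs4 (4.3 ± 0.94), the neurite growth factor Nrn1 (3.51 ± 0.75), Nrsn1 (3.15 ± 0.65), Stmn2 (2.68 ± 0.58) and the neuropeptide Cck (2.52 ± 0.48). Genes of dividing cells that fell were Cdkn3 (-3.11 ± 0.39), Mki67 (-2.78 ± 0.26), Kif15 (-2.68 ± 0.26) and Pimreg (-2.56 ± 0.21). The myeloid genes Cd93 (-3.04 ± 0.39) and Pf4 (-2.86 ± 0.62) fell too. Adjusted p for these genes ran up to 0.0475.

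Of the 24 cell cycle genes 14 fell and 10 did not pass, with a median of -1.26 and 21 lower adjusted over the list alone (camera adjusted p = 2.54e-19; adjusted p = 0.0983 with an estimated correlation). Examples are Top2a (-2.29 ± 0.22), the ribonucleotide reductase subunit Rrm1 (-2.19 ± 0.31) and the cyclin Ccnb2 (-2.12 ± 0.4). Of 16 microglia markers 5 fell and 11 did not pass, with a median of -1.93 (camera adjusted p = 1.62e-08; adjusted p = 0.391 with an estimated correlation). Those that fell included the complement genes C1qc (-2.48 ± 0.49) and C1qa (-2.01 ± 0.44), the leukocyte phosphatase Ptprc (-2.1 ± 0.42) and the lysozyme gene Lyz2 (-2 ± 0.31). Medians of the other non-neuronal lists were -0.29 for astrocytes, -0.01 for oligodendrocytes, -0.09 for endothelial and mural cells, -0.98 for oligodendrocyte precursors and -0.5 for fibroblast, meningeal and choroid plexus cells. Of their members 1 fell, in the last of these lists. The precursor list passed camera (adjusted p = 0.0157; adjusted p = 0.391 with an estimated correlation). The fibroblast list did not (adjusted p = 0.0713). The extracellular matrix gene Fn1 fell by 2.54 ± 0.43.

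Of 10 excitatory neuron markers 1 rose, the vesicular glutamate transporter Slc17a6 (2.14 ± 0.41), 9 did not pass, and 9 rose adjusted over the list alone. The median was 1.72 (camera adjusted p = 3.18e-05; adjusted p = 0.391 with an estimated correlation). Of 8 CA1 pyramidal markers 1 rose, the transcription factor Pou3f1 (1.21 ± 0.26; its CA3 means were 3.58 at T0 and 3.69 at 12 h), with a median of 1.21 (camera adjusted p = 0.000259; adjusted p = 0.27 with an estimated correlation). Of 7 CA2 markers 2 rose, Pcp4 (2.15 ± 0.4) and the calcium-binding protein gene Necab2 (1.04 ± 0.17), with a median of 0.18 (camera adjusted p = 0.032; adjusted p = 0.331 with an estimated correlation). The spike signal was lowest at 12 h, and with it as a covariate the medians were 0.95 for excitatory neuron, 1.1 for CA1, -0.88 for microglia and -1.09 for cell cycle genes.

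Of 36 immediate early genes 5 rose and 31 did not pass (median 0.64, camera adjusted p = 7.64e-09; adjusted p = 0.27 with an estimated correlation). Besides Gadd45b, Gadd45g and Fosb they included Ptgs2, the inducible cyclooxygenase (1.9 ± 0.33). Bdnf stood at 3.71 ± 0.93 (adjusted p = 0.0715) and Arc, a regulator of synaptic receptors, at 1.98 ± 0.53 (adjusted p = 0.0846), not past the threshold. Of 33 unfolded protein and integrated stress response genes 5 rose, 1 fell and 27 did not pass (median 0.25, camera adjusted p = 0.0325; adjusted p = 0.391 with an estimated correlation). Beside Chac1, the pseudokinase Trib3 rose by 1.38 ± 0.23 and Herpud1, of endoplasmic reticulum protein degradation, by 1.37 ± 0.26, while the co-chaperone Dnajc3 fell by 1.4 ± 0.26. Of 22 NRF2 targets 2 rose, Srxn1 (1.62 ± 0.32) and the autophagy receptor Sqstm1 (1.23 ± 0.26, while 3 other probe sets of Sqstm1 lay at 0.07, 0.12 and 0.22), and the list did not shift (median -0.08, camera adjusted p = 0.901). Hmox1 was 0.61 ± 0.34 (adjusted p = 0.394). The cytosolic ribosomal protein list had a median of -0.71, with all 30 lower and 1 past the threshold, Rps15a (-1.04 ± 0.2; list camera adjusted p = 1.72e-10; adjusted p = 0.391 with an estimated correlation).

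At 12 h 328 probe sets passed averaged over both regions, 133 higher and 195 lower, standing for 264 genes. The pair means left 0 (limma; 1664 at an unadjusted p under 0.05), with Chac1 nearest at adjusted p = 0.0541, and the spike signal as a covariate left 3. Without the replicate 2 arrays of 30 min and 12 h, 1 passed. Leaving out single arrays gave 55 (without CA3 T12h replicate 2) to 474 probe sets, and 11 of the 16 moved the count by over 1.5 times. In simulated data whose pairs share deviations, with 200 of 15866 probe sets changed, 36.2% of the calls of this fit were false. That share depends on the number changed and on deviations drawn independently between probe sets, so it is no estimate for the 328.

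**Figure D3:**
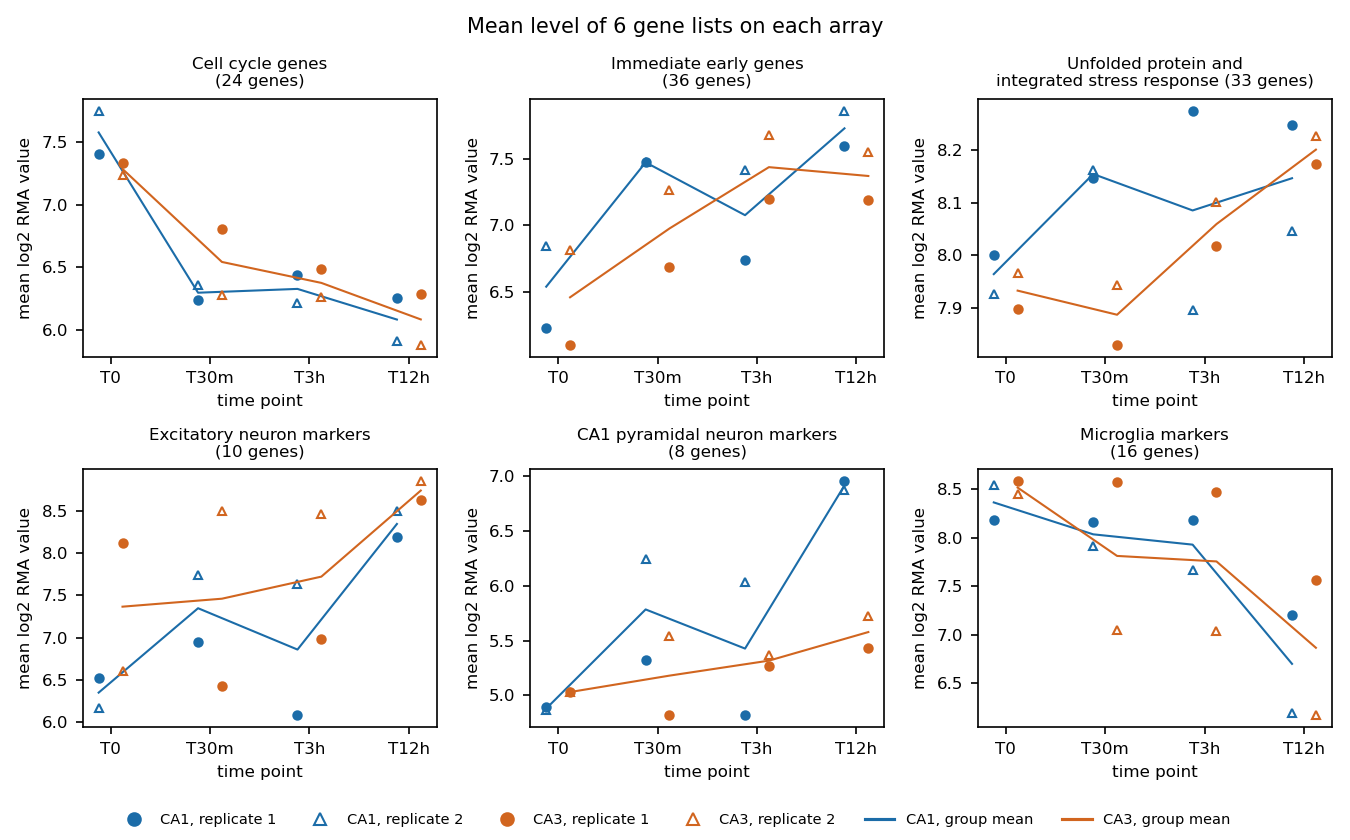
Mean log2 RMA value (vertical axis) of 6 gene lists on each array, by time point (horizontal axis). Points are arrays, 2 per region and time, and lines join group means. The cell cycle list is lower on every later array than on the T0 arrays, while the excitatory neuron list differs widely between replicates at T0 in CA3, at 30 min and at 3 h.

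Within regions, the 12 h change was tested in CA1 and CA3 apart. In CA1, Kif15 fell by 3.15 ± 0.37, Mki67 by 3.06 ± 0.36 and Top2a by 2.65 ± 0.31 (adjusted p = 0.014 for each). Cdkn3 (-3.33 ± 0.55), Cd93 (-3.67 ± 0.55) and Rrm1 (-2.73 ± 0.44) fell too. Genes that rose in CA1 were Gadd45b (3.37 ± 0.41), Chac1 (2.89 ± 0.28), Pou3f1 (2.31 ± 0.37), the activin subunit Inhba (2.07 ± 0.31), the ubiquitin ligase Siah2 (1.78 ± 0.28) and the heparan sulfate epimerase Glce (1.18 ± 0.19), among others. In CA3 the gene that passed was Chac1 (3.41 ± 0.28, adjusted p = 0.00213). There Gadd45b was 3.17 ± 0.41, Pimreg -2.21 ± 0.3 and Glce 1.43 ± 0.19 (adjusted p = 0.0806 for each). The cell cycle list had a median of -1.29 in CA1 and -1.08 in CA3, and the microglia list -1.83 and -1.87.

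In CA1 33 probe sets passed at 12 h (8 higher and 25 lower) and in CA3 1 (2 arrays against 2). The difference between these counts is no test of a difference between regions. Without the CA1 T0 replicate 2 array 0 passed in CA1, with the spike covariate 3, and without the CA3 T0 replicate 1 array 10 passed in CA3.

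The series' main question, whether CA1 and CA3 respond differently, was tested by the difference between the regions' changes. The leading genes did not pass: at 12 h Pou3f1 differed by 2.21 ± 0.52, the matrix proteoglycan Dcn by 3.36 ± 0.85, Cfap90 by 1.77 ± 0.29 and the nicotinic receptor modulator Lynx1 by -1.16 ± 0.28 (adjusted p = 1 for each), with positive values for a larger change in CA1. At 30 min the leading genes included Gpr85 (1.84 ± 0.51) and Dcn (2.87 ± 0.85), and at 3 h Exosc7 (-1.1 ± 0.3) and Chst10 (0.92 ± 0.25). As a list, CA1 pyramidal markers changed more in CA1 at 12 h, with a median of 2.12 in CA1 and 0.46 in CA3 and a median difference of 1.54 over 8 genes (camera adjusted p = 2.07e-08; adjusted p = 0.0799 with an estimated correlation). These genes were picked as markers of CA1 neurons, so a rise of neuronal genes in both regions would raise them more in CA1. Excitatory neuron markers rose in both, with medians of 2.07 in CA1 and 1.4 in CA3. The list therefore cannot show that the regions respond differently.

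For this difference 0 probe sets passed at 30 min, 3 h and 12 h and 0 in the F test over all times (limma; 133, 55, 71 and 61 at an unadjusted p under 0.05). The pair fit gave 0 for each (595, 281, 371 and 394). Camera passed 6, 2 and 10 of 39 lists at 30 min, 3 h and 12 h, and 0 with an estimated correlation.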

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

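Gene lists whose change against T0 differed between CA1 and CA3 by camera on the difference itself are given here, as the median over genes of the CA1 change minus the CA3 change (log2). Of 117 combinations of list and time 18 passed at the preset correlation, and 0 with an estimated correlation, where adjusted p ran from 0.0799 to 0.96. The pair fit was chosen after these results were seen.

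Among neuron and glia lists, CA1 pyramidal markers differed by 0.46 at 30 min and 1.54 at 12 h (changes of 2.12 in CA1 and 0.46 in CA3), and excitatory neuron markers by 0.49 at 12 h (2.07 and 1.4). The CA1 list holds genes picked as markers of CA1 neurons, so a larger change in CA1 can follow from that choice alone. The excitatory list was lower in CA1 at T0 (median -0.99, all 10 genes lower), and this offset enters its difference at 12 h. Oligodendrocyte markers differed by -0.68 at 30 min, with medians of -0.11 in CA1 and 0.58 in CA3, and by -0.37 at 12 h (-0.36 and 0.03). Fibroblast, meningeal and choroid plexus markers differed by 0.45 at 30 min, where the pair fit did not pass (adjusted p = 0.052), and by 0.2 at 12 h. This list too was lower in CA1 at T0, with a median of -0.35 and 1 of 12 genes higher (camera adjusted p = 0.000338; adjusted p = 0.636 with an estimated correlation). That offset enters both of its differences.

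The fall of cell cycle genes was larger in CA1, by a median difference of -0.49 at 30 min (-1.33 in CA1 and -0.59 in CA3), -0.23 at 3 h and -0.21 at 12 h. At T0, however, this list was higher in CA1 (median 0.33, 18 of 24 genes, camera adjusted p = 0.000332, and 0.636 with an estimated correlation). At 3 h its CA1 minus CA3 median was 0.02. The differences at all times share this T0 offset. At 30 min the mean difference over the genes was -0.54, beside a T0 mean of 0.29, so the offset does not make up all of it. That difference did not pass with an estimated correlation (camera adjusted p = 0.497). A stronger response in CA1 is thus not shown. Immediate early genes differed by 0.39 at 30 min and 0.18 at 12 h, and by -0.36 at 3 h, where their median change was 0.36 in CA1 and 0.82 in CA3. Unfolded protein and integrated stress response genes differed by 0.26 at 30 min. At 12 h the cytosolic ribosomal proteins differed by -0.28, antioxidant enzymes by -0.31, mitochondrial complex I subunits by -0.23 and proteasome subunits by -0.24. No explanation was tested for these differences.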

How the results depend on the processing

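Counts of probe sets or lists past the threshold that moved by over 1.5 times are given by setting. The pair fit, the spike and GAPDH covariates and the sets of arrays left out together were chosen after the results were seen. With an intensity trend, the 30 min and 3 h changes in CA1 gave 10 and 8, and the 12 h change in CA3 4; the robust prior gave 0 for CA1 at 3 h. With the replicate number as a block CA1 gave 6, 10 and 153 at 30 min, 3 h and 12 h, CA3 22 at 12 h, and both regions averaged 49, 92 and 1302. The numbers deviate together among the later times, but 5 of 12 correlations with T0 were under 0.1. Probe sets above the median level gave 0, 0 and 11 in CA1, 2 in CA3 at 12 h, 3, 11 and 206 averaged, and 5 and 12 lists at 30 min and 12 h. Array weights gave 19 and 0 in CA1 at 30 min and 3 h, 45 in CA3 at 12 h, and 27 and 758 averaged at 30 min and 12 h. Fits of the compared groups alone gave 0, 0 and 0 in CA1, 0 in CA3 at 12 h, and 0, 1 and 598 averaged.

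An estimated correlation left 1 list for region and 0, 0 and 0 for the averaged times. Fry passed 1 list for region and 1, 1 and 7 for the averaged times. Within regions, the cell cycle list passed camera with an estimated correlation in CA1 at 30 min and 3 h (adjusted p = 0.0451 and 0.0425). In CA3 it did not (adjusted p = 0.298 and 0.134), and at 12 h 0 lists passed in each region. The pair fit gave 33 probe sets and 21 lists for region and 0, 0 and 0 probe sets for the averaged times. The spike covariate gave 0 and 3 in CA1 at 30 min and 12 h, 2 in CA3 at 12 h, 2 and 3 averaged at 30 min and 12 h, and 5, 5 and 10 lists. The GAPDH covariate gave 9 and 512 in CA1 at 3 h and 12 h, 34 in CA3 at 12 h, 69, 50 and 2014 averaged, and 5 lists at 3 h. Without the replicate 2 arrays of 3 h, CA1 gave 0, 0 and 14, CA3 1 at 3 h, the averages 3 and 0 at 30 min and 3 h, and the lists 5 at 3 h. Without those of 30 min and 12 h, CA1 gave 0, 0 and 0, CA3 0 at 12 h, the averages 0, 1 and 1, and the lists 4 at 30 min.

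Leaving out each array in turn, with the lone array of its group assumed to vary like the other groups, gave these lowest and highest counts. They were, for region, 0 and 0, region at T0 0 and 6 (the latter without CA3 T0 replicate 1). In CA1 they were 0 and 4 at 30 min, 0 and 4 at 3 h, 0 and 35 at 12 h. In CA3 they were 0 and 5 at 30 min, 0 and 5 at 3 h, 1 and 10 at 12 h. Averaged over both they were 0 and 18, 0 and 51, 55 and 474. Differences between the regions' changes gave 0 and 1 at each time and 0 and 0 in the F test. Lists gave 7 (without CA1 T3h replicate 1) and 16 for region, 3 and 17 at 30 min, 4 and 17 at 3 h, and 13 and 23 at 12 h.

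For named genes past the threshold, 1295 of 2019 values under other settings stayed past it, 724 did not, and 0 reversed direction. Of all 3609 values for named genes, 71 gained the threshold and 0 reversed. Many of these values could not reverse, so the absence of reversals says little about direction. The intensity trend, the robust prior, the number as a block and the compared groups alone leave the log2 change as it is. So does leaving out an array that a contrast does not use.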

Other observations

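The tests of explanations and the regroupings in this part, except the tests that leave out a pair of arrays, were chosen after the results they bear on were seen. Several further gene groups were measured. At 12 h the 18 interferon response genes had a median of -0.36 and the 14 complement and antigen presentation genes one of -0.63 with 2 members falling, C1qc and C1qa, which the microglia list also holds (camera adjusted p = 0.00634 and 0.00736; adjusted p = 0.391 for each with an estimated correlation). The microglia median was -1.93 beside them. Of the 14 complement genes 7 are in another list and 4 in the microglia list, and the other 10 had a median of -0.37. Of 29 inflammatory cytokine and NF-kappaB target genes 1 was above 0 and rose, Ptgs2, and the median was -0.41 (camera adjusted p = 0.0109; adjusted p = 0.594 with an estimated correlation). The chemokine gene Cxcl1 was at -2.29 ± 0.97 (adjusted p = 0.244), with T0 values in CA3 that differed widely (5.42 in replicate 1 and 8.92 in replicate 2). Oligodendrocyte precursor markers had a median of -0.98 over 6 genes with 0 past the threshold, Vcan at -1.58 ± 0.44 and Ptprz1 at -1.48 ± 0.43 (camera adjusted p = 0.0157; adjusted p = 0.391 with an estimated correlation). The interneuron list did not shift (median 0.31, camera adjusted p = 0.274), with Reln at -2.05 ± 0.54 and Sst at 1.38 ± 0.5 (adjusted p = 0.0831 and 0.175).

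At 12 h Slc2a1, the glucose transporter, rose (1.32 ± 0.29, adjusted p = 0.0497), with the neuronal glucose transporter Slc2a3 at 2.41 ± 0.7 (adjusted p = 0.106). The clock repressor Nfil3 also rose (1.54 ± 0.21, adjusted p = 0.00771), with Clock at 0.97 ± 0.29 (adjusted p = 0.113), as did Inhba (2.02 ± 0.22, adjusted p = 0.00267). Calcium channel and calcium-binding genes had a median of 0.24 (camera adjusted p = 0.00326; adjusted p = 0.391 with an estimated correlation), with the channel subunit Cacnb3 at 0.84 ± 0.22 (adjusted p = 0.0846). At 3 h the 34 mitochondrial complex I subunits had a median of -0.22 and the 30 subunits of complexes III to V one of -0.34, with 0 past the threshold in each (camera adjusted p = 0.0115 and 0.0109; adjusted p = 0.665 for each with an estimated correlation). The heat shock gene Hspa1a was at 2.16 ± 0.8 at 12 h (adjusted p = 0.184), and at 0.44 without the low-spike replicate 2 arrays of 30 min and 12 h.

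The cell cycle list was lower at 30 min already, with a median of -1. Amplification or input, as far as the spike signal measures it, is argued against as the whole cause. With that covariate the median was -0.82 (camera adjusted p = 2.28e-15, and 0.218 with an estimated correlation, against 0.0561 without the covariate). RNA quality is argued against by -1.14 with the GAPDH 3' to 5' covariate (adjusted p = 0.0568 with an estimated correlation), and a single pair of arrays by medians of at most -0.79 when each T0 or 30 min pair was left out. T0 cultures that stand apart from all later ones, in handling or state, stay open as a candidate explanation. The median at 30 min was 0.79 of that at 12 h, but this restates the pattern, and both medians share the T0 arrays, so it does not speak for the explanation. A response of dividing cells to the treatment stays open as well and was not tested, since no array of untreated cultures at a later time was analysed here.

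Excitatory neuron markers were higher and microglia markers lower at 12 h. With the spike signal as a covariate the medians were 0.95 (from 1.72) and -0.88 (from -1.93), and both lists still passed camera (adjusted p = 0.0318 and 0.000569), but not with an estimated correlation (adjusted p = 0.753 for each with the covariate and 0.391 for each without it). For the part of the shift that was lost, time cannot be told apart from what the spike signal measures. The signal was lower on all 12 h arrays than on all T0 arrays. The hybridization control BioB was low on the 12 h replicate 2 arrays as well, so the signal may hold more than amplification or input. A lower share of all other cell types to the same degree is argued against by the oligodendrocyte median of -0.01 (quartiles -0.52 and 0.19). The microglia quartiles were -2.03 and -1.64. The other lists lay between, at -0.98 for oligodendrocyte precursors, -0.5 for fibroblast, meningeal and choroid plexus cells, -0.29 for astrocytes and -0.09 for endothelial and mural cells. An unequal fall of other cell types is thus not argued against. Low signals limit the oligodendrocyte list, with mean log2 values of 4.7 for Mog and Mal and 4.3 for Ugt8. Of the 16 microglia genes 4 are in another list, and of the 10 excitatory neuron genes 0. A loss of microglia or of their transcripts, or a difference between cultures in neuron survival, may account for this and was not tested.

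Oligodendrocyte markers were lower in CA1. The spike covariate left a median of -0.57 (from -0.59; adjusted p = 0.0603 with an estimated correlation, from 0.0459), and the GAPDH 3' to 5' covariate one of -0.54 (adjusted p = 0.175 with an estimated correlation). So the call with an estimated correlation was lost with each covariate, while the median moved little. Leaving out each pair left -0.45 at the nearest to 0. More of all non-neuronal cells in the CA3 samples is argued against by the astrocyte median of 0.15 (quartiles 0.03 and 0.34) beside oligodendrocyte quartiles of -0.8 and -0.44, though fibroblast, meningeal and choroid plexus markers had a median of -0.21. Whether the regions themselves or the amount of white matter taken with each dissected field differ stays open and was not tested.

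Regroupings of the arrays bear on chance, and each count of regroupings includes the real one. Of 128 exchanges of the region labels within pairs 100 were run. In the pair fit 1 of these, the real labelling itself, gave 33 probe sets, with 15 as the highest other count. For lists at the preset correlation 1, again the real labelling, gave 21, with 19 as the highest other. Counts this high were thus rare among the exchanges run, by a narrow margin for lists. Chance is not excluded, since the other exchanges were not run and the pair fit was chosen after the data were seen. With an estimated correlation 0 lists passed in the pair fit.

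For the times, splits of the 8 arrays of T0 and a later time that keep pairs together number 3, too few for a share under 0.05. In a fit of those 8 arrays with region as a term, the real and highest other counts of probe sets were 14 and 91 at 3 h (2 of 3 splits as large) and 1161 and 15 at 12 h (1 of 3). At 30 min they were 0 and 36, and with a real count of 0 all 3 splits give as many whatever the data, so nothing follows there. The 36 and the 91 came from the split by replicate number, which points to structure that follows the number, and a split at 30 min that parts pairs and does not follow the number gave 61. With the number as a block in the fit of all arrays, 49 and 92 passed at 30 min and 3 h. For lists the real and highest other counts were 7 and 17 (2 of 3), 10 and 16 (2 of 3) and 21 and 14 (1 of 3). Over all 34 splits that could be fitted, parted pairs included, 34 at 30 min (where the real count is 0), 2 at 3 h and 1 at 12 h gave as many probe sets. For lists 17, 18 and 2 gave as many at 30 min, 3 h and 12 h, with another split at 12 h reaching 21.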
